A study of Rattus norvegicus with 18 samples.

How the data were processed

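The samples came from NRK-52E, an established rat line with features of kidney proximal tubule epithelium. Per the labels, confluent cells in plates received aristolochic acid (AA) at 1.65 µM in 0.1% DMSO, or 0.1% DMSO alone, for 6, 24 or 72 h. The dose was the concentration that inhibited the cells by 10 percent at 72 h, per the labels' protocols. Aristolochic acid is a nitrophenanthrene carcinogen of Aristolochia plants that forms bulky DNA adducts after metabolic reduction and injures the proximal tubule. Total RNA was extracted with Trizol, turned into biotin-labelled cRNA by the manufacturer's protocol and hybridised to Affymetrix rat arrays, per the labels. The 18 arrays formed 6 groups of 3, called AA or DMSO with the hour. The labels call the 3 samples of a group biological replicates and do not say whether they shared a plate or a day, so p-values measure the spread between these samples.

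The values were the authors' deposited log2 expression values, 1 per probe set and array. GCRMA, which corrects background from probe sequence, normalizes between arrays and summarises probes, is named in the submitters' processing notes. Its version, its settings, the scanner files and a genome build are not given in the sources used here. The array medians lay between log2 4.03 and 4.20. Many values sat near log2 2, the floor that GCRMA gives to weak probe sets, and no detection calls were used here. A group mean below log2 4 is therefore close to that floor, and a fold change against it depends on the background model. For arrays, the number of arrays limits the precision; the median SD between replicates of a group was 0.11 on the log2 scale.

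Of 31099 probe sets, 57 were controls. The platform annotation gave 1 gene symbol to 20832 probe sets, several to 436 and none to 9831, and only probe sets with 1 symbol were used for genes. Of those, 20764 were matched by gene number to current rat names in a RefSeq table of assembly GRCr8. This gave 14217 genes. A gene with several probe sets was represented by the one with the highest mean over all arrays. Genes with log2 4 or more on at least 3 arrays were tested, which left 9015.

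All 18 arrays were fitted together in R 4.3.3 with limma 3.58.1, using 6 group means, empirical Bayes moderation with an intensity trend (12 residual degrees of freedom, 7.27 prior) and Benjamini-Hochberg adjustment within each comparison. Adjusted p under 0.05 counted as passing the test. The comparisons were AA against DMSO at each time, the difference of that effect between 24 h and 6 h and between 72 h and 24 h, and DMSO at 24 h against 6 h and at 72 h against 24 h. Treatment comparisons at different times share no arrays. Time comparisons in DMSO share arrays with the treatment comparisons.

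Before the data were examined, 41 gene lists were fixed from textbook knowledge, with 1384 members written, of which 1191 were on the array. Lists with at least 5 tested members (36 of 41) were tested with limma's camera, which compares a list with all other genes, at a preset inter-gene correlation of 0.01. The AhR target, core histone, endothelial, immune cell and loop, distal and collecting duct lists had too few tested members. Camera with a correlation estimated for each list and fry, which tests each list by itself, were alternatives. List tests on time comparisons in DMSO and on differences between times were added after the treatment comparisons had been seen.

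The genes named were also set by rule before the data were examined. For each treatment comparison they were the 10 largest increases and 10 largest decreases among genes past the test whose 3 AA arrays all lay on one side of the 3 DMSO arrays, up to 4 called members of each list past camera, and a set named whatever its test (Cdkn1a, Mdm2, Ccng1, Gadd45a, Btg2, Bax, Nqo1, Cyp1a1, Hmox1, Havcr1, Ccl2, Tgfb1, Cdh1 and Vim). For differences between times and for DMSO time comparisons they were the 5 largest each way. Btg2 and Bax had no probe set with a single symbol in the annotation used and are not analysed here. Cyp1a1, Havcr1, Ccl2 and Cdh1 fell below the filter, with means over all arrays of log2 2.69, 1.91, 2.66 and 2.57.

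The steps were tested on simulated data built from the real means and spreads, with genes changed only in AA at 72 h among 9015. Of 67 genes changed by log2 0.5, 65.7% were recovered, of 67 changed by 1, 97.0%, and of 66 changed by 2, 100%. False calls made up 3.68% of the calls. At 6 h and 24 h, where nothing was changed, 0 genes were called. The p53 list, whose members were also raised, was found, and 0 other lists were. The simulated noise was independent between genes, so the run cannot show how often camera calls lists whose members vary together.

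RNA quality was read from the 3' minus 5' log2 difference of the beta-actin, Gapdh and hexokinase control probe sets. Hybridisation was read from the BioB spike-in. Each was compared with a two-sided exact permutation test. With 3 arrays against 3 the smallest p of that exact test is 0.1. The hexokinase and BioB readouts were added after the others had been planned. No pair of arrays was identical (0 pairs; highest correlation 0.996). Alternatives covered the replicate number as a block, the arrays fitted, the filter, the moderation, another scaling, the probe set rule, array weights, the threshold, the list test and each array left out in turn. Gene spans were taken as annotated lengths in GRCr8, which 99.7% of tested genes had. Figures were drawn with matplotlib 3.10.9.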

Results

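Expression was measured on 18 arrays of NRK-52E cells, 3 for each of the groups DMSO 6 h, AA 6 h, DMSO 24 h, AA 24 h, DMSO 72 h and AA 72 h. The comparisons ask which genes differed between cells exposed to 1.65 µM AA and solvent controls of the same age, and how that difference moved with time. A gene said to rise or fall at a time was higher or lower in AA than in DMSO at that time. Comparisons between times within DMSO are named as such. Values are log2 expression; ± after a log2 fold change is its standard error, and ± after a level is the SD of the 3 arrays. Genes whose lower group lay under log2 4 are marked as near the floor. Replicates of a group correlated across probe sets with r between 0.984 and 0.996. The first principal component, with 53.8% of the variance, ordered the groups by time. The second, with 22.3%, set AA 72 h apart from every other group. On the fourth, with 4.89%, AA 6 h replicate 3 lay at -26.5 while the other AA 6 h arrays lay at -6.63 and -8.92.

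**Figure D1:**
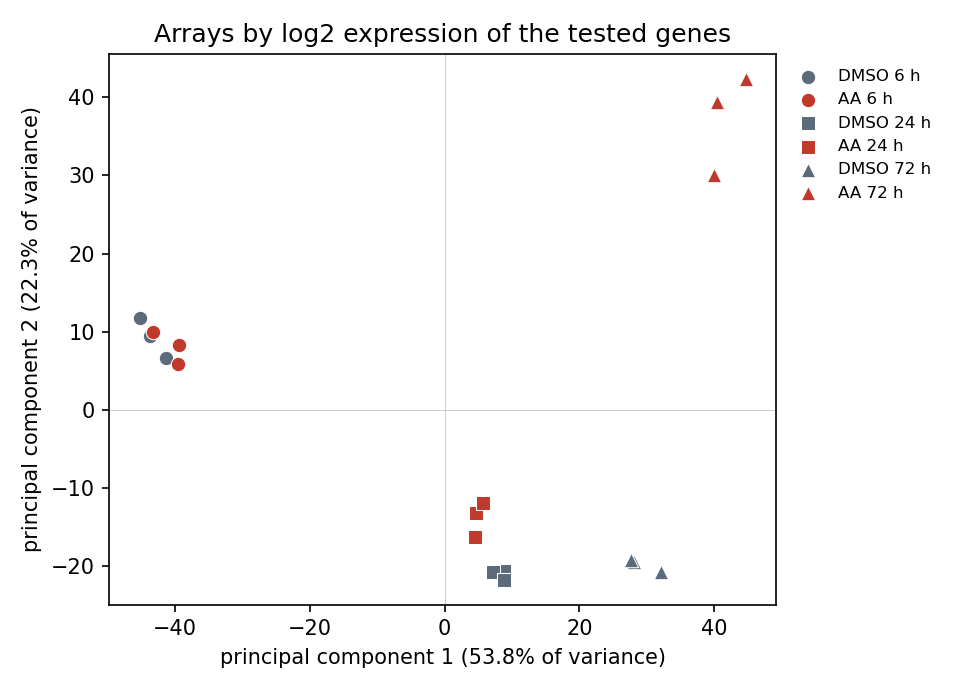
Each point is an array placed by its scores on the first (x) and second (y) principal components of the log2 values of the 9015 tested genes, with 53.8% and 22.3% of the variance; color gives the treatment and shape the time. The highest AA 72 h array lies at 42.3 on the second component, and the DMSO 72 h arrays lie between -20.7 and -19.2.

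At 6 h the largest increase was in Nppb, the gene of the B-type natriuretic peptide, which rose by a log2 fold change of 2.51 ± 0.35 from a level near the floor (adjusted p = 0.000238, n = 3). Adamts1, a secreted metalloprotease, rose by 1.56 ± 0.31, and Gys1, a glycogen synthase, by 1.56 ± 0.29. The largest decrease was in Hey2, a transcriptional repressor of the Notch pathway, at -2.02 ± 0.29 and near the floor (adjusted p = 0.000265, n = 3). Cdkn1a, the p21 inhibitor of cyclin-dependent kinases and a main p53 target, was higher, at 11.97 ± 0.14 against 11.29 ± 0.06 in DMSO (log2 fold change 0.68, adjusted p = 0.000182, n = 3). The list of p53 targets did not pass camera at 6 h. Of its genes 3 rose and 5 fell, with a median of 0.11, and with centred arrays 5 rose and 3 fell.

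Other large increases at 6 h were in Tnfaip6, a hyaluronan-binding protein (1.51 ± 0.41), Dact2, a Wnt pathway modulator (1.41 ± 0.20), Slc17a6, a vesicular glutamate transporter (1.67 ± 0.39), Tmem51 (1.40 ± 0.37) and A3galt2 (1.41 ± 0.28). Ankrd1, a muscle ankyrin repeat protein and YAP target, rose by 1.69 ± 0.44 and Veph1 by 1.63 ± 0.32, both from near the floor. Depdc7 fell to a log2 fold change of -1.89 ± 0.29 and the zinc finger gene Plag1 to -1.75 ± 0.24. Further decreases, all to levels near the floor, were in Sp4 (-1.88), the arginase gene Arg2 (-1.87), the nuclear receptor gene Nr4a3 (-1.81), Tchh (-1.63), the complement inhibitor gene Serping1 (-1.57), Zfp819 (-1.49) and the carboxypeptidase gene Cpm (-1.49). Tgfb1 rose by 0.58 (adjusted p = 0.023) and the intermediate filament gene Vim by 0.32 (adjusted p = 0.00581). Without DMSO replicate 3, Tmem51 was at 0.68 and Tnfaip6 at 0.88 (adjusted p = 0.0745). Tgfb1 lost its call in 4 other settings, Ankrd1 and Tnfaip6 in 3 each, Tmem51 in 2 and Serping1 in 1. Other genes named in advance did not pass: Mdm2 at 0.24 (adjusted p = 0.137), Ccng1 at 0.12 (0.200), Gadd45a at -0.20 (0.259), Nqo1 at -0.23 (0.306) and Hmox1 at -0.25 (0.512).

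In all, 2211 of 9015 genes passed the limma test at 6 h, 1091 higher and 1120 lower, with a median absolute log2 fold change of 0.43. Of these, 48 rose and 56 fell by at least 2-fold. The 3 AA arrays did not overlap the 3 DMSO arrays for 3284 genes, 36.4% of those tested, where chance gives 10%. Centring each array on its median gave 2345 genes, 1707 higher and 638 lower, so the balance of directions followed the scaling. The median log2 of the arrays was 4.06 in AA and 4.13 in DMSO (exact permutation p = 0.1, the smallest possible). The count was 579, 293 higher and 286 lower, when only the 6 h arrays were fitted, 900 without AA replicate 3, the array apart on the fourth component, and 1414 without DMSO replicate 2.

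Among the fixed lists at 6 h, 15 of 29 glycolysis and hypoxia genes rose and 0 fell, with 14 not passing. Adjusted over the list alone, 16 rose. They included the hexokinase gene Hk2 (0.94), the phosphofructokinase gene Pfkl (0.85), the mitophagy receptor gene Bnip3 (0.71) and the glucose transporter gene Slc2a1 (0.67). The list median was 0.30 (camera adjusted p = 6.83e-06; adjusted p = 0.803 with an estimated correlation). Of 33 proteasome genes, 15 rose, 0 fell and 18 did not pass, with 19 up when adjusted over the list alone. Psmb7 rose by 0.46, Psmb5 by 0.37, Psmd1 by 0.36 and Psmc1 by 0.31. The median was 0.18 (camera adjusted p = 1.03e-05; adjusted p = 0.803 with an estimated correlation). Of 52 oxidative phosphorylation genes, 15 rose and 37 did not pass, and 15 rose adjusted over the list alone. The complex I subunit genes Ndufs8 (0.55), Ndufv1 (0.41), Ndufa9 (0.34) and Ndufb3 (0.33) were among them. The median was 0.14 (camera adjusted p = 0.000199; adjusted p = 0.821 with an estimated correlation). With centred arrays 20 glycolysis, 22 proteasome and 22 oxidative phosphorylation genes rose, and without AA replicate 3, 6, 2 and 1. Without that array Hk2 was at 0.54, Pfkl at 0.45, Bnip3 at 0.43, Slc2a1 at 0.37, Psmb5 at 0.23, Ndufv1 at 0.26 and Ndufb3 at 0.20, and of these only Bnip3 passed. Pfkl and Ndufa9 lost their calls in 5 other settings each, Hk2, Ndufv1 and Psmb5 in 3, Slc2a1, Ndufs8 and Ndufb3 in 2, and Bnip3 and Psmd1 in 1.

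Lipid genes rose in part at 6 h. Of 21 cholesterol synthesis genes 5 rose and 16 did not pass, with 6 up adjusted over the list alone, among them Pmvk (0.87), Lss (0.68), Fdft1 (0.59) and Fdps (0.57), enzymes of the mevalonate and sterol pathway. The median was 0.32 (camera adjusted p = 0.000627; adjusted p = 0.821 with an estimated correlation). Of 13 fatty acid synthesis genes 5 rose and 1 fell, with 7 up and 1 down adjusted over the list alone. The desaturase genes Fads2 (0.70) and Scd2 (0.52) and Mid1ip1 (0.43) rose, and the acyltransferase gene Gpam fell (-1.04). The median was 0.38 (camera adjusted p = 0.0167; adjusted p = 0.821 with an estimated correlation). Of 20 fatty acid oxidation and PPAR targets 8 rose and 2 fell, with 9 and 3 adjusted over the list alone. Acaa2 (0.68), Eci1 (0.65) and the lipid droplet gene Plin2 (0.61) rose, and Pdk4, which restrains pyruvate oxidation, fell (-0.69). The median was 0.16 (camera adjusted p = 0.0331; adjusted p = 0.821 with an estimated correlation). Pdk4 lost its call in 10 other settings, Lss in 6, Fdft1 and Gpam in 4 each, Fads2 and Mid1ip1 in 3, Fdps in 2, and Plin2 and Scd2 in 1. Without AA replicate 3, Fads2 was at 0.38, Fdft1 at 0.34, Fdps and Lss at 0.36 each and Pdk4 at -0.45. Pdk4 was at -1.04 without DMSO replicate 1 and at -0.42 without DMSO replicate 3. With centred arrays 13 cholesterol synthesis genes rose, 8 fatty acid synthesis genes rose and 1 fell, and 9 PPAR targets rose and 0 fell. Without AA replicate 3, 1 cholesterol synthesis gene rose, and 1 fatty acid synthesis gene, whose list call ended (camera adjusted p = 0.126). That call also ended without DMSO replicate 3 (0.0505), and that of the PPAR targets without AA replicate 1 (0.0502) or DMSO replicate 1 (0.126).

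Of 16 heat shock genes 7 rose and 9 did not pass at 6 h, with 8 up and 1 down adjusted over the list alone. The chaperone genes Hspb8 (0.53), Hspa4 (0.45), Hspb1 (0.39) and Hsph1 (0.35) rose (list median 0.20, camera adjusted p = 0.0126; adjusted p = 0.803 with an estimated correlation). Of 16 MAPK feedback and EGFR ligand genes 6 rose and 1 fell, with 7 and 1 adjusted over the list alone. The ERK phosphatase gene Dusp6 (1.13), the EGFR ligand gene Btc (1.04) and, near the floor, Fosl1 (1.61) rose, and Etv5 fell (-0.84). That list had a median of 0.26 (camera adjusted p = 0.0411; adjusted p = 0.803 with an estimated correlation). Of 25 SRF, YAP and cytoskeleton genes 7 rose and 2 fell, the same numbers as adjusted over the list alone. They included the actin-binding protein genes Tpm2 (0.56), Cnn2 (0.47) and Tagln (0.44), and the median was 0.22 (camera adjusted p = 0.0423; adjusted p = 0.821 with an estimated correlation). Of 55 G2/M genes 4 rose, Spc24 (0.72), Ccnb2 (0.57), Nuf2 (0.41) and Cenpk (0.38), and 51 did not pass, with 2 up adjusted over the list alone. Their median was 0.16 (camera adjusted p = 0.0423; adjusted p = 0.921 with an estimated correlation). Without AA replicate 3 only Spc24 rose and the list call ended (camera adjusted p = 0.504), as it did without DMSO replicate 1 (0.417) or AA replicate 1 (0.0612). Of 30 autophagy and lysosome genes 8 fell and 1 rose, with 9 and 1 adjusted over the list alone. The lysosomal membrane protein genes Lamp2 (-0.44) and Lamp1 (-0.31), and Atg12 (-0.35) and Ulk1 (-0.32), which act in autophagosome formation, fell. That list's median was -0.10 (camera adjusted p = 0.0196; adjusted p = 0.803 with an estimated correlation), and with centred arrays 2 of its genes rose and 2 fell. With centred arrays 11 heat shock genes rose and 0 fell, and 11 SRF and YAP genes rose and 1 fell. For MAPK genes these counts were 8 and 1, and for G2/M genes 6 and 0. Without AA replicate 3, 4 heat shock genes rose and 2 lysosome genes fell. List calls also ended for MAPK genes without AA replicate 2 or DMSO replicate 3 (camera adjusted p = 0.144 each), for SRF and YAP genes without AA replicate 2 (0.192), DMSO replicate 2 (0.0717) or DMSO replicate 3 (0.180), and for lysosome genes without DMSO replicate 3 (0.0508). With the replicate number as a block the SRF and YAP call ended too (0.0509). Ulk1 lost its call in 11 other settings, Nuf2 in 9, Hspb8, Cenpk and Lamp1 in 6 each, Atg12 and Btc in 4, Fosl1 and Tagln in 3, Ccnb2 in 2, and Hspa4, Hsph1, Lamp2 and Tpm2 in 1. Fosl1 on AA replicate 1 lay within the range of DMSO and lost its call without AA replicate 2 or 3. Without AA replicate 3, Ccnb2 was at 0.37, Lamp1 at -0.18 and Lamp2 at -0.25, and without DMSO replicate 3 Atg12 was at -0.23 and Ulk1 at -0.20.

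At 24 h, genes of cell division and DNA replication were higher in AA, and Cdkn1a was higher with them. Kif18b, a mitotic kinesin, rose by a log2 fold change of 1.38 ± 0.20 (adjusted p = 0.000637, n = 3), from 6.28 ± 0.56 in DMSO to 7.66 ± 0.13. Pole2, a subunit of DNA polymerase epsilon, rose by 1.36 ± 0.29, a call lost in 5 other settings. Cdkn1a rose by 1.12 ± 0.09 (adjusted p = 1.32e-06, n = 3), from 10.93 to 12.04. The largest decrease was in Slc9a9, an endosomal sodium and proton exchanger, at -1.63 ± 0.32 and near the floor, a call lost in 2 other settings.

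Of 55 G2/M and mitosis genes, 46 rose at 24 h, 0 fell and 9 did not pass; adjusted over the list alone, 53 rose. Ncaph, a condensin subunit (1.22 ± 0.18), Cdca2 (1.23 ± 0.18), the kinesin gene Kif15 (1.10 ± 0.16) and Spc24 of the kinetochore (1.05 ± 0.16) were among them. The list median was 0.85 (camera adjusted p = 7.44e-75; adjusted p = 0.0203 with an estimated correlation). Of 43 G1/S and DNA replication genes, 22 rose and 21 did not pass, with 36 up adjusted over the list alone. Besides Pole2, the histone chaperone gene Asf1b (0.99) and the helicase complex genes Gins3 (0.82, lost in 6 other settings) and Cdc45 (0.81) rose. The median was 0.51 (camera adjusted p = 2.04e-37; adjusted p = 0.0152 with an estimated correlation). These were the 2 of 13 lists past camera at 24 h whose call held with an estimated correlation.

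Of 25 genes of homologous recombination and Fanconi anaemia repair, 7 rose, 1 fell and 17 did not pass at 24 h, with 11 up and 1 down adjusted over the list alone. Brca1, near the floor in DMSO, rose by 1.35 ± 0.24, Rad51ap1 by 1.17, the recombination motor gene Rad54l by 0.99 and Fancd2 by 0.83. The median was 0.29 (camera adjusted p = 5.82e-06; adjusted p = 0.0600 with an estimated correlation). Of 31 p53 targets, 7 rose, 0 fell and 24 did not pass, with 13 up adjusted over the list alone. With Cdkn1a they included the exonuclease gene Aen (0.87), Notch1 (0.74) and Phlda3 (0.60). The median was 0.24 (camera adjusted p = 4.03e-10; adjusted p = 0.0594 with an estimated correlation). Mdm2, whose product degrades p53, did not pass at 0.43 (adjusted p = 0.0774), nor did Ccng1 at 0.25 (adjusted p = 0.0812). Hmox1 was at 0.44 (adjusted p = 0.583), Vim at 0.14 (0.535), Tgfb1 at 0.10 (0.899), Nqo1 at 0.02 (0.987) and Gadd45a at -0.00 (1.0). In other lists past camera few members passed. In the list of 16 senescence-associated secreted factors, Areg (0.86) and Cdkn1a, whose product is not secreted, rose. Adjusted over the list alone, 3 rose (camera adjusted p = 5.82e-06, and adjusted p = 0.0987 with an estimated correlation). Ier3 (0.47) and Ier5 (0.45) rose of 26 immediate early genes, with 3 adjusted over the list alone (0.000706; adjusted p = 0.448 with an estimated correlation). Areg rose of 16 MAPK feedback genes, with 3 adjusted over the list alone (0.0251; adjusted p = 0.503 with an estimated correlation). A single member passed, also when adjusted over the list alone, in each of the lists of 27 NRF2 targets (Ephx1, 0.51), 13 Wnt and Notch targets (Notch1) and 10 mesenchymal genes (S100a4, 0.54). Their camera adjusted p were 0.00852, 0.0231 and 0.0265, against adjusted p = 0.626, 0.448 and 0.448 with an estimated correlation. Of 9 fibroblast, 52 oxidative phosphorylation and 33 proteasome genes 0 passed, over all genes or adjusted over the list alone, with medians of 0.32, 0.05 and 0.06. Their camera adjusted p were 0.0186, 0.0231 and 0.0259, against adjusted p = 0.606, 0.669 and 0.669 with an estimated correlation. List calls of the MAPK, Wnt and Notch, mesenchymal and fibroblast genes ended without AA replicate 1 (camera adjusted p = 0.0930, 0.225, 0.161 and 0.265) or DMSO replicate 1 (0.0828, 0.153, 0.0899 and 0.0899). That of the mesenchymal genes ended without DMSO replicate 3 too (0.0905). Those of oxidative phosphorylation and proteasome genes ended without DMSO replicate 3 (0.839 and 0.145), the former also without AA replicate 2 (0.0698) and the latter without AA replicate 3 (0.107). Areg lost its call in 10 other settings, Ier5 in 7, Rad51ap1 and S100a4 in 6 each, Ephx1 in 5, Fancd2 in 3, Notch1 in 2, and Aen and Phlda3 in 1. Rad51ap1 was at 0.78 without DMSO replicate 3.

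Further increases at 24 h were in Clspn (1.36), a mediator of the replication checkpoint, Sapcd2 (1.26) and Tube1 (1.23), all near the floor in DMSO, and in Cenpt of the kinetochore (1.29) and Ddias (1.22). Mob1b, a Hippo pathway adaptor, fell by 1.40, Arhgap26 by 1.29 and Map2k6, a kinase upstream of p38, by 1.15, the last pair near the floor. Decreases were also found in Rnf180 (-1.27), the adaptor gene Sh3kbp1 (-1.19), Cfap69 (-1.10), Ank2 (-1.06), the guidance receptor gene Robo2 (-1.03) and Trappc9 (-1.03, adjusted p = 0.0493). Of the 10 largest decreases at 24 h, 6 span over 300 kb in GRCr8 and 2 span 100 to 300 kb. Of the 10 largest increases, 0 span over 300 kb. Among all 8984 genes with a span, 181 exceed 300 kb. Trappc9 lost its call in 10 other settings, Robo2 in 7, Cfap69 and Rnf180 in 6 each, Ddias in 5, Sapcd2 in 4, and Ank2, Map2k6 and Tube1 in 1. In all, 188 genes passed the limma test at 24 h, 163 higher and 25 lower, with 23 up and 10 down by at least 2-fold. Groups did not overlap for 1754 genes (19.5%, where chance gives 10%). With array weights 388 passed, 229 higher and 159 lower. The count was 100 without AA replicate 1, 104 without AA replicate 2, 106 without DMSO replicate 1 and 102 without DMSO replicate 3.

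**Figure D2:**
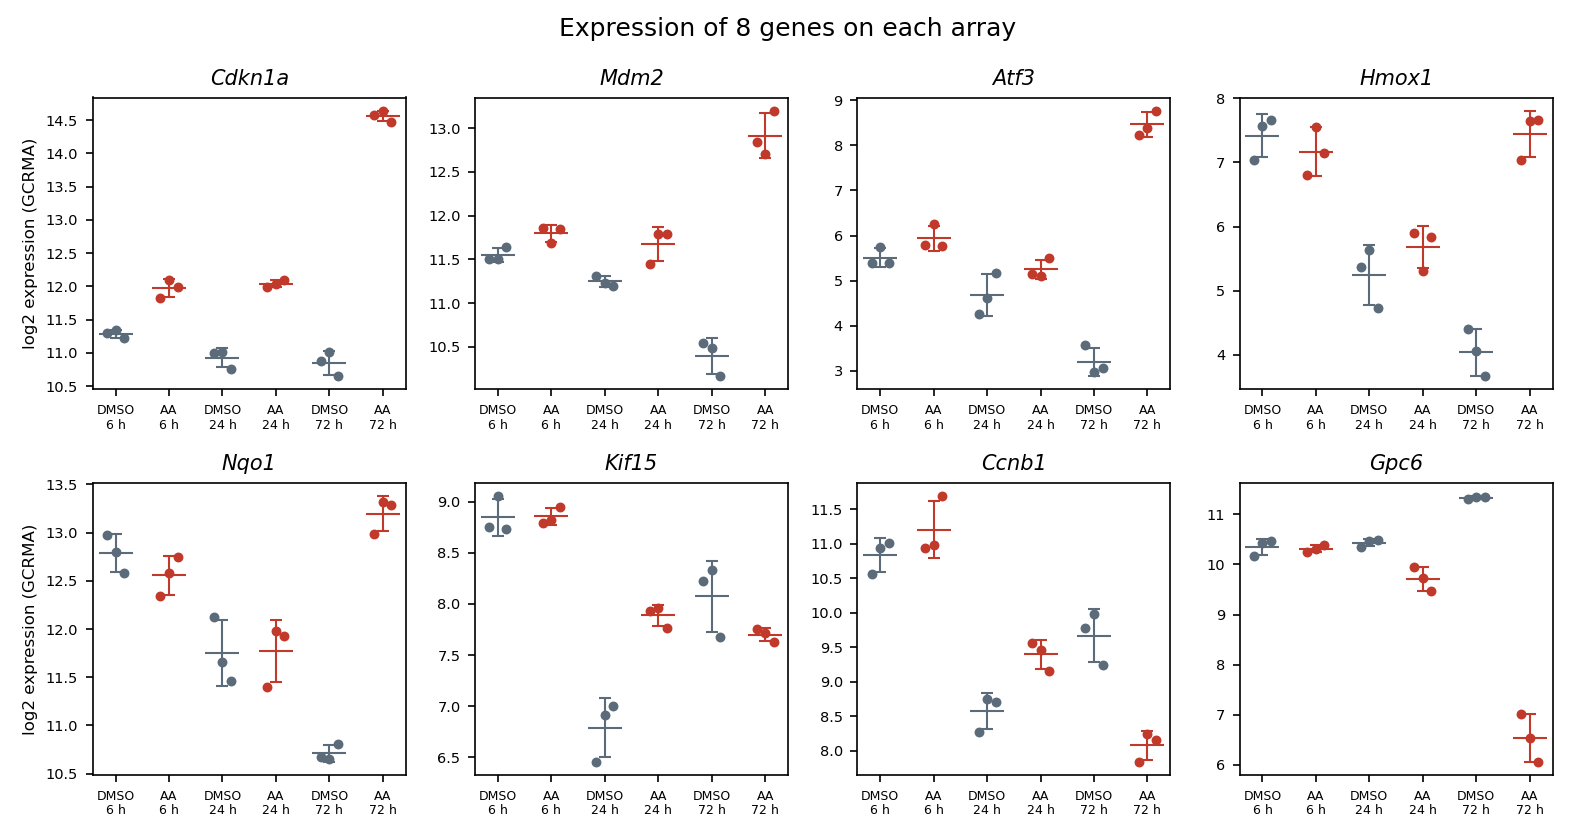
Each panel shows the log2 expression (GCRMA, y) of a gene in the 6 groups (x); points are arrays, bars the group mean and whiskers the SD of 3 arrays. Cdkn1a differed from DMSO by 0.68, 1.12 and 3.71 at 6, 24 and 72 h, while Gpc6 at 72 h was 6.54 in AA and 11.33 in DMSO.

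At 72 h 47.2% of the tested genes differed, and most p53 targets and oxidant defence genes had risen. Cdkn1a rose by a log2 fold change of 3.71 ± 0.09 to 14.56 ± 0.08, against 10.85 ± 0.18 in DMSO (adjusted p = 1.56e-16, n = 3). Mdm2 rose by 2.51 ± 0.12 (adjusted p = 2.7e-12). Hmox1, the heme oxygenase gene, rose by 3.41 ± 0.26 (adjusted p = 2.85e-09), and Nqo1, a quinone reductase that can activate AA, by 2.49 ± 0.16. The largest increase was in Pln, the gene of the calcium pump regulator phospholamban, by 6.67 ± 0.16 from the floor (adjusted p = 1.56e-16). The largest decrease was in Cfap299, at -5.43 ± 0.14 and to near the floor (adjusted p = 4.27e-16).

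Of 31 p53 targets, 22 rose, 3 fell and 6 did not pass at 72 h, the same as adjusted over the list alone. Gdf15, a stress cytokine, rose by 3.68 from near the floor, the kinase gene Plk2 by 2.77, Phlda3 by 2.70 and Ccng1 by 1.90. The median was 0.76 (camera adjusted p = 2.12e-09; adjusted p = 0.227 with an estimated correlation). Gadd45a, another target named in advance, rose by 1.37. Of 27 NRF2 targets 22 rose and 2 fell, also when adjusted over the list alone. Osgin1 (4.34, from near the floor), the glutathione transferase gene Gsta1 (3.19) and the aldo-keto reductase gene Akr1b8 (3.15) joined Hmox1. The median was 1.02 (camera adjusted p = 1.96e-09; adjusted p = 0.280 with an estimated correlation). Of 32 genes of the ATF4 stress response 19 rose and 2 fell, with 20 and 2 adjusted over the list alone. Atf3 (5.27, from near the floor), Trib3 (3.56), the folate enzyme gene Mthfd2 (2.86) and Sesn2 (2.32) rose most, with a median of 0.51 (camera adjusted p = 3.54e-05; adjusted p = 0.309 with an estimated correlation). The beta-actin 3' minus 5' difference, a sign of RNA quality, was 2.0 ± 0.16 in AA and 1.35 ± 0.09 in DMSO at 72 h (SD, n = 3, exact permutation p = 0.1, the smallest possible). For Gapdh it was -0.07 and -0.21 (exact permutation p = 0.1).

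Of 26 immediate early genes 20 rose and 1 fell at 72 h, the same as adjusted over the list alone, among them Klf4 (2.25), Ier5 (1.64) and Egr2 (1.49). The median was 0.72 (camera adjusted p = 6.63e-06; adjusted p = 0.309 with an estimated correlation). Of 25 SRF, YAP and cytoskeleton genes 20 rose and 0 fell, with 21 up adjusted over the list alone. Ankrd1 (2.81, from near the floor), the fibronectin receptor gene Itga5 (1.40), Tagln (1.36) and Ccn1 (0.76) were among them. Their median was 0.47 (camera adjusted p = 1.01e-05; adjusted p = 0.309 with an estimated correlation). In the list of 16 senescence-associated secreted factors 12 rose and 1 fell, also when adjusted over the list alone. Besides Gdf15 and Cdkn1a, whose product is not secreted, these included Vegfa (2.19) and Areg (1.63). The median was 0.46 (camera adjusted p = 3.54e-05; adjusted p = 0.280 with an estimated correlation). Of 29 glycolysis and hypoxia genes 21 rose and 1 fell, with 22 and 1 adjusted over the list alone, including Ddit4 (2.24), Pfkl (1.32) and Slc2a1 (1.04). The median was 0.44 (camera adjusted p = 8.11e-06; adjusted p = 0.415 with an estimated correlation). Of 33 proteasome genes 18 rose and 0 fell, with 19 up adjusted over the list alone, including Psmb7 (0.80), Psmc5 (0.66), Psmd1 (0.59) and Psma4 (0.46). Their median was 0.20 (camera adjusted p = 0.00721; adjusted p = 0.646 with an estimated correlation). Of 21 cholesterol synthesis genes 11 rose and 1 fell, also when adjusted over the list alone, including Mvd (1.46), Tm7sf2 (1.31), Hsd17b7 (1.07) and Idi1 (0.79). Their median was 0.39 (camera adjusted p = 0.0453; adjusted p = 0.782 with an estimated correlation), and the list call ended without AA replicate 2 (0.0669), AA replicate 3 (0.0746) or DMSO replicate 3 (0.104), where Tm7sf2 was at 0.87. Tgfb1 rose by 1.40, and Vim did not pass at -0.10 (adjusted p = 0.295). The actin 3' minus 5' difference was 0.65 higher in AA across these arrays.

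G2/M and mitosis genes, which were higher in AA at 24 h, were lower at 72 h, when 38 of 55 fell, 4 rose and 13 did not pass. Adjusted over the list alone, 39 fell and 4 rose. The anaphase activator gene Cdc20 (-1.84), the cyclin gene Ccnb1 (-1.59), Cenpf (-1.44) and the kinase gene Plk1 (-1.44) fell. The median was -0.59 (camera adjusted p = 5.1e-09; adjusted p = 0.487 with an estimated correlation). Of 40 cytosolic ribosomal protein genes 30 fell, 1 rose and 9 did not pass, with 32 down and 1 up adjusted over the list alone. Rps9 (-0.70), Rpl21 (-0.51), Rpl12 (-0.48) and, near the floor, Rpl28 (-0.52, lost in 8 other settings) fell. The median was -0.24 (camera adjusted p = 1.96e-09; adjusted p = 0.331 with an estimated correlation), and 24 of these genes fell under quantile normalization and with centred arrays. These arrays differed by 0.65 in the actin 3' minus 5' measure.

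Further genes that rose at 72 h from near the floor were Spetex2l2 (4.93), Slc51a, a subunit of the basolateral organic solute transporter (4.84), Pinlyp (4.39), Phlda2 (4.06) and Hapln3 (3.88). Gpc6, a cell surface heparan sulfate proteoglycan gene, fell by 4.79 ± 0.16, from 11.33 ± 0.03 to 6.54 ± 0.47. Bbs9, of the ciliary BBSome, fell by 4.07 ± 0.16. Decreases to near the floor were found in the sugar kinase gene Fggy (-5.25), Gmds of fucose synthesis (-5.09) and the autophagy gene Atg10 (-4.36). Trappc9 (-4.16), Gtdc1 (-4.13) and the propionyl-CoA carboxylase gene Pcca (-4.11) fell to near it too. The cytokine gene Il33 was near the floor in AA, at -4.04 against DMSO, and lay there in both 24 h groups. Of the 10 largest decreases at 72 h, 8 span over 300 kb in GRCr8 and 1 spans 100 to 300 kb. Of the 10 largest increases, 0 span over 300 kb. Among all 8984 genes with a span, 181 exceed 300 kb. In all, 4257 genes passed the limma test at 72 h, 2472 higher and 1785 lower, with 386 up and 437 down by at least 2-fold. Groups did not overlap for 5372 genes (59.6%, where chance gives 10%). Among these arrays too the actin 3' minus 5' measure was 0.65 higher in AA.

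**Figure D3:**
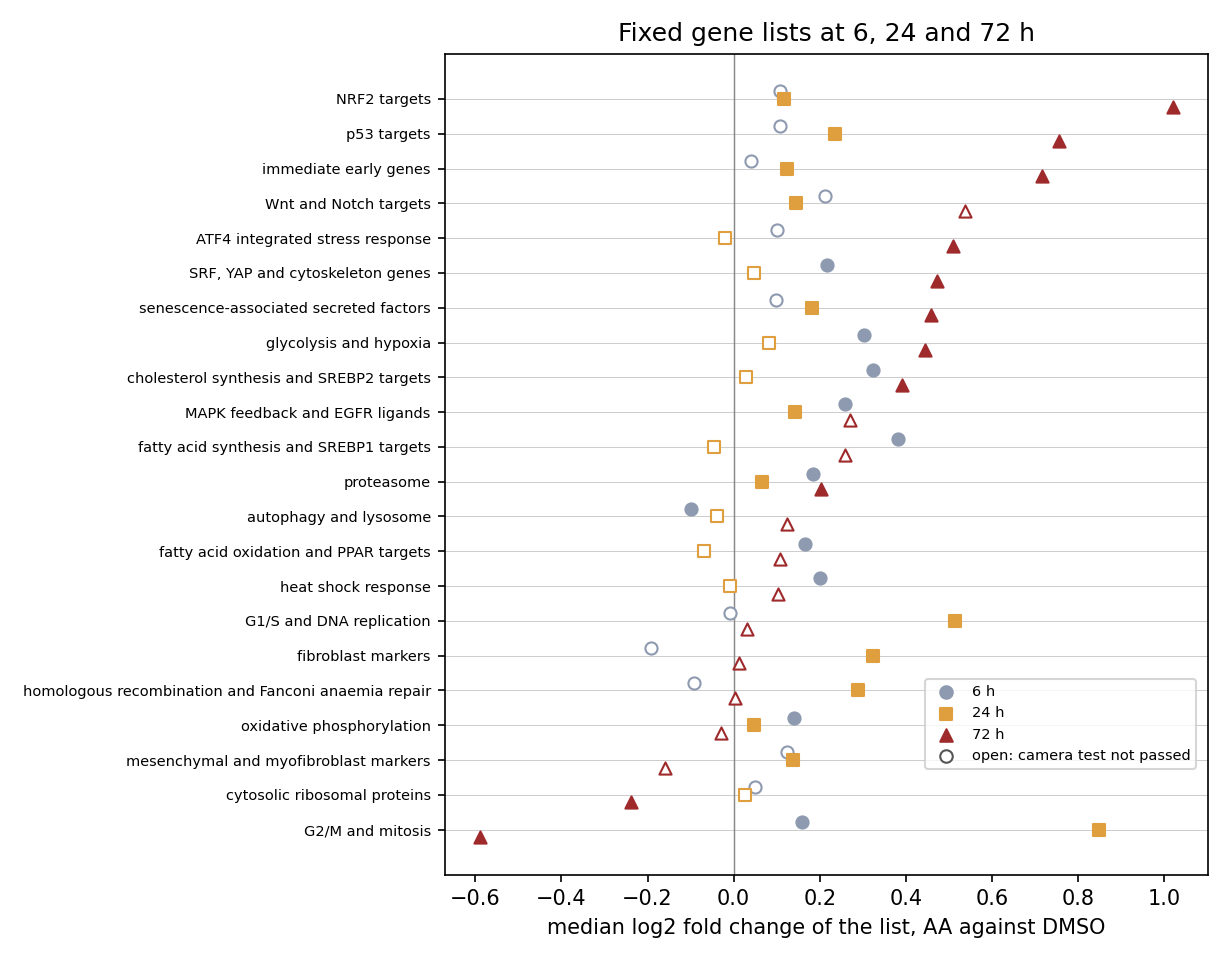
The median log2 fold change (x, AA against DMSO) is shown for every fixed list (y) past camera at any of the times 6 h (circles), 24 h (squares) and 72 h (triangles), filled where the list passed at that time with the preset correlation. G2/M genes had medians of 0.16, 0.85 and -0.59, and p53 targets 0.11, 0.24 and 0.76.

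The response itself differed between times. Between 24 h and 6 h the AA effect differed in 219 genes, 131 with a higher and 88 with a lower value at 24 h. Dact2, raised by 1.41 at 6 h, was at -0.04 at 24 h, a difference of -1.46. Of the 219, 6 genes, Nppb and Hey2 among them, lay near the floor in both 24 h groups and 1 in both 6 h groups, so for these the effect at that time could not be measured. Of the 10 genes with the largest differences, 3 kept their call in each setting that tested them at the same threshold; Gys1 lost it in 15, Arg2 in 12, Depdc7 and Robo2 in 11 each, and Dact2, Hey2 and Nppb in 2 each. The count was fragile. It ran from 22 without AA 24 h replicate 2 to 458 without AA 6 h replicate 1, and with centred arrays it was 182, 75 higher and 107 lower. It was also 96 without AA 6 h replicate 3, 330 without DMSO 6 h replicate 1, 32 without DMSO 6 h replicate 2 and 100 without DMSO 6 h replicate 3. At 24 h it was 94 without AA replicate 1, 83 without AA replicate 3, 130 without DMSO replicate 1, 86 without DMSO replicate 2 and 123 without DMSO replicate 3. Between 72 h and 24 h the effect differed in 2921 genes, 1683 higher and 1238 lower at 72 h. Of these, 49 lay near the floor in both 24 h groups and 3 in both 72 h groups. Atf3 differed by 4.70 and Cfap299 by -4.90, each near the floor in a 72 h group. For 49 of 55 G2/M genes the effect was lower at 72 h than at 24 h, for 0 it was higher and for 6 the difference did not pass, with 51 lower adjusted over the list alone (median -1.42; adjusted p = 0.277 with an estimated correlation).

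In DMSO alone, many genes differed between times, which gives the background for the treatment effects. No batch is given, so time in culture and a batch shared by the samples of a time cannot be told apart. From 6 h to 24 h, all 55 G2/M genes fell, with a median of -2.03 (adjusted p = 0.142 with an estimated correlation), and 41 of 43 G1/S genes fell, with a median of -1.58 (adjusted p = 0.121). Of 40 ribosome biogenesis and MYC targets 35 fell (median -0.66, adjusted p = 0.142), and 19 of 20 fatty acid oxidation and PPAR targets rose (median 0.58, adjusted p = 0.142), each p with an estimated correlation. These counts were the same adjusted over the list alone. The clock output gene Dbp rose by 3.70 and Tm7sf2 by 3.28, and, from near the floor, the clock gene Per3 by 3.24, Zc3h6 by 3.43 and Veph1 by 3.07. Mlf1 (-3.74) and the carbonic anhydrase gene Car3 (-3.38) fell, and Etv5 (-3.63), Clspn (-3.56) and Rasa3 (-3.29) fell to near the floor. In all, 5296 genes passed, 2549 higher and 2747 lower at 24 h, and 5793 did not overlap (64.3%, where chance gives 10%).

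From 24 h to 72 h in DMSO, all 55 G2/M genes rose, with a median of 1.09 (adjusted p = 0.324 with an estimated correlation). Of 21 cholesterol synthesis genes 18 fell, with 21 down adjusted over the list alone and a median of -1.41 (adjusted p = 0.324 with an estimated correlation). Of 33 proteasome genes 24 fell, with 25 down and 1 up adjusted over the list alone (median -0.29, adjusted p = 0.339 with an estimated correlation). Of 27 NRF2 targets 17 fell and 2 rose, with 19 and 2 adjusted over the list alone (median -0.41, adjusted p = 0.339 with an estimated correlation). Aqp1, the water channel of the proximal tubule, rose by 5.22, Pkhd1l1 by 4.20, Il33 by 3.96 and Angptl4 by 2.92, all from near the floor, and the matrix proteoglycan gene Fmod by 2.59. Tm7sf2 (-3.91), Mfap4 (-3.69) and Mvd (-3.56) fell, and Poteml2 (-4.24) and the skeletal actin gene Acta1 (-3.72) fell to near the floor. For Il33, Aqp1, Tm7sf2 and Mvd the 72 h effects of AA ran against these changes in DMSO. Those effects are differences from DMSO at 72 h, not changes with time in AA. In all, 3095 genes passed, 1551 higher and 1544 lower at 72 h, and 4744 did not overlap (52.6%, where chance gives 10%).

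Increases at 24 h and 72 h overlapped in 50 genes, where independent lists of these sizes would share 44.7, and decreases in 19 against 4.95. Of the genes raised at 24 h, 52 were lowered at 72 h, against 32.3 for independent lists. At 6 h and 24 h, increases shared 19 genes against 19.7 for independent lists, and decreases 10 against 3.11. At 6 h and 72 h, increases shared 354 against 299, and decreases 213 against 222. Across genes, which are not independent replicates, the effects at 24 h and 72 h correlated with r = 0.25, at 6 h and 24 h with 0.31, and at 6 h and 72 h with 0.07. Other probe sets of the named genes, with log2 4 or more on at least 3 arrays, went the same way in 19 of 19 cases at 6 h, 9 of 11 at 24 h and 16 of 16 at 72 h. Of those, 4, 2 and 2 moved by less than 0.5 of the named probe set's change, with those of Plin2 and Tpm2 at 0.00 at 6 h. The exceptions at 24 h were probe sets of Robo2 (0.22 against -1.03) and Tube1 (-0.08 against 1.23).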

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

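The test of whether cell cycle genes lay between the control levels was chosen after the result was seen. The idea about long genes came from the names of the genes that fell most at 72 h, before spans were computed, and AA 6 h replicate 3 had been seen apart before its test. List tests on differences between times, the spans among genes with the highest means and the counts of genes near the floor in both groups of a time were also added after the results had been seen.

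The effect of AA differed between times by a test of the difference itself in 219 genes for 24 h against 6 h and in 2921 genes for 72 h against 24 h; 212 and 2869 of these were not near the floor in both groups of either time. Of 100 drawn splits of the arrays, 6 gave as many genes as the 219, so these splits do not exclude chance, and the highest other split gave 1742. The 5 others all exchanged AA and DMSO at 6 h, a structure of the samples: they carry the 6 h response and do not measure chance alone. The split with 1742 kept 24 h and so tested the sum of the 24 h and 6 h effects. For the 2921, 2 of 100 splits gave as many, under a share of 0.05. The highest other, with 2952 genes, kept the 72 h groups and mixed the 24 h arrays. Most drawn splits mixed the 72 h groups and so thinned the 72 h effect, which by itself makes a low share likely. These splits therefore do not tell whether the effect differed between 72 h and 24 h beyond chance.

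The largest differences between 24 h and 6 h were found in Arg2 (2.15), Hey2 (2.02), Tube1 (1.83), Depdc7 (1.73), Nr4a3 (1.71), Robo2 (-1.40), Dact2 (-1.46), Gys1 (-1.59), Nppb (-2.42) and Veph1 (-2.46), as the effect at 24 h minus that at 6 h on the log2 scale. Arg2, Hey2, Nr4a3 and Nppb lay near the floor in both 24 h groups, so their 24 h effect could not be measured, and Tube1 and Veph1 in their lowest group. Of these 10 genes 3 kept their call in each setting that tested them at the same threshold; Gys1 lost it in 15, Arg2 in 12, Depdc7 and Robo2 in 11 each, and Dact2, Hey2 and Nppb in 2 each. Those between 72 h and 24 h were found in Pln (6.66), Atf3 (4.70), Spetex2l2 (4.45), Slc51a (4.41), Osgin1 (4.0), Il33 (-3.97), Gpc6 (-4.07), Gmds (-4.50), Fggy (-4.87) and Cfap299 (-4.90), all but Gpc6 near the floor in their lowest group. Pln, Spetex2l2, Slc51a and Il33 lay there in both 24 h groups, so their 24 h effect could not be measured either.

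Genes with long spans were lower in AA at 72 h: the 181 tested genes that span over 300 kb in GRCr8 had a median log2 fold change of -1.60, 155 lower and 6 higher, against 0.09 for 2161 genes under 10 kb (rho = -0.264 across 8984 genes). Low expression of long genes as the whole cause is argued against by the 2995 genes with the highest means, where the 40 over 300 kb had a median of -0.65 (35 lower, 2 higher) against 0.04 for 756 under 10 kb; rho there was -0.183, but -0.180 at 6 h, when genes over 300 kb had not shifted (-0.00). RNA quality as read from beta-actin is argued against for the smaller 24 h shift. There long minus short genes were at -0.22 (-0.25 to -0.19 without each array) while actin differed by -0.02. In DMSO, genes over 300 kb rose by a median of 0.41 from 6 h to 24 h (89 higher, 22 lower), against -0.01 under 10 kb. A lag of treated wells behind that change therefore stays open for the 24 h shift. RNA quality stays open at 72 h. There the lower 95% bound of the slope within groups, times the actin difference of 0.65, reaches -0.825 of the observed -1.65. That product extrapolates beyond the spread within groups. Reduced transcription of long genes, which bulky DNA adducts may cause by stalling RNA polymerase, is a candidate explanation, tested only on the data it came from.

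Many genes changed by small amounts at 6 h. The count of 2211 fell to 900 without AA 6 h replicate 3, of which 875 were among the 2211, to 1414 without DMSO 6 h replicate 2 and to 579 when only the 6 h arrays were fitted. All 2211 genes kept their direction without either array, but genes chosen as past the test with these same arrays would seldom reverse. The called genes at 24 h and 72 h all kept their direction too, without each array. A steady trend of the 6 h fold change with mean expression among the tested genes is argued against by rho = 0.0224. Other forms of normalization that depends on intensity stay open, as this rho cannot detect them. The array medians over all probe sets averaged log2 4.06 in AA and 4.13 in DMSO, while the tested genes had a median log2 fold change of 0.0076. On AA 6 h replicate 3 the actin 3' minus 5' difference was 0.98, against 1.27 and 1.26 on its replicates and 1.14 to 1.17 in DMSO. Hexokinase was at 0.87 against 1.09 and 1.12, and Gapdh at -0.30 against -0.22 on both. These last readouts lay within the DMSO 6 h ranges of 0.67 to 1.14 and -0.34 to -0.23. A stronger response and a technical deviation of AA 6 h replicate 3 both stay open, as no batch is given.

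Cell cycle genes were higher in AA at 24 h. In DMSO they fell from 6 h to 24 h, and the 89 genes with over 2-fold change lay back towards the 6 h level by a median fraction of 0.371. A general lag of treated wells as the whole cause is argued against, since 993 other genes that changed in DMSO lay back by 0.0676 (463 that fell by 0.112, 530 that rose by 0.0460), where noise alone gives 0.0188. A smaller lag of all genes stays open. The other genes lay back by more than noise gives, but they include cell cycle genes outside the fixed lists, such as Clspn. That excess therefore cannot tell whether genes in general lagged. The 24 h effect and the DMSO change had a covariance of -0.0515 across genes, where shared arrays give -0.0112. That covariance includes the cell cycle genes, so it cannot tell whether other genes lagged. Slower withdrawal from the cycle and arrest in S or G2 phase cannot be told apart, since either would place genes that fell in DMSO between its 24 h and 6 h levels, where 98.9% of the cell cycle genes lay.

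With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split was 1 of 10 with as many genes at 6 h (2211, highest other 47), at 24 h (188, highest other 0), at 72 h (4257, highest other 0), and in DMSO for 24 h against 6 h (5296, highest other 0) and 72 h against 24 h (3095, highest other 0). For gene lists past camera, 2 of 10 splits gave as many at 6 h (11, highest other 13), 1 of 10 at 24 h (13, highest other 12) and 5 of 10 at 72 h (11, highest other 17). Each other split mixes 2 arrays of a group with 1 of the other group. It so keeps part of the real difference and adds the rest to the spread. Neither the gene counts nor the list counts of these splits therefore measure chance alone.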

How the results depend on the processing

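All settings given here were chosen before the data were examined. At 72 h, 60 of 61 named genes past the test stayed past it in each setting that tested them at the same threshold, Rpl28 being the exception; at 24 h 16 of 37 did and at 6 h 28 of 66. Among the values of named genes in these settings, 3450 kept their direction and side of the threshold, 290 lost and 8 gained a call, and 11 reversed. Replicate numbers did not pair the arrays (own number best in 2 of 9); with the number as a replicate block within each time, 2077, 170 and 4150 genes passed at 6, 24 and 72 h, and 174 and 2782 for the differences between times. With that block, SRF and YAP genes lost their list call at 6 h (adjusted p = 0.0509). Signal near the floor limits genes under log2 4.

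The cause of the following moves was not tested unless stated. Fitting only the arrays of the times compared gave 579 genes at 6 h and 89 for 24 h minus 6 h. It gave 156 at 24 h and 5087 for DMSO 24 h against 6 h. At 72 h (4384), for 72 h minus 24 h (3237) and for DMSO 72 h against 24 h (3555) it gave more genes than the full fit. These fits differ from the full fit both in degrees of freedom and in the arrays that set the spread. The counts therefore cannot tell which of these lowered the number at 6 h. Without a filter, with more genes tested, 112 passed at 24 h, 78 for 24 h minus 6 h, and 7 lists at 6 h. Moderation without trend gave 138 for 24 h minus 6 h. Every probe set on its own, with more features tested, gave 3482 at 6 h, 7236 at 72 h, 4804 for 72 h minus 24 h, 8715 for DMSO 24 h against 6 h and 5720 for DMSO 72 h against 24 h. Array weights gave 388 at 24 h, 229 higher and 159 lower against 163 and 25, with 1172 for 24 h minus 6 h and 4707 for DMSO 72 h against 24 h. Requiring a log2 fold change of 0.58, a stricter rule, gave 600 at 6 h, 1880 at 72 h, 1832 for 72 h minus 24 h, 2640 for DMSO 24 h against 6 h and 1141 for DMSO 72 h against 24 h. Adjusted p under 0.01, stricter too, gave 931 at 6 h, 91 at 24 h, 5 for 24 h minus 6 h, 1777 for 72 h minus 24 h and 2001 for DMSO 72 h against 24 h. An estimated correlation left 0, 2 and 0 lists at 6, 24 and 72 h, and fry called 5 at 24 h and 25 at 72 h.

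Leaving out each array gave 900 to 2537 genes at 6 h, 100 to 203 at 24 h, 3629 to 4207 at 72 h, 22 to 458 for 24 h minus 6 h, 2417 to 3136 for 72 h minus 24 h, 4813 to 5017 for DMSO 24 h against 6 h and 2457 to 2711 for DMSO 72 h against 24 h. Lists ran from 8 to 10 at 6 h, 9 to 15 at 24 h and 10 to 12 at 72 h. The reversals were all at 24 h in genes that did not pass. Gadd45a, at -0.00, was at 0.0056 with quantile normalization, 0.034 with centred arrays, 0.025 with array weights, 7.55e-05 without DMSO replicate 2, 0.0043 without DMSO replicate 3, and between -0.067 and 0.074 without each array, the highest without AA replicate 1. Tgfb1, at 0.10, was at -0.038 without AA replicate 1 and up to 0.23 without the others. Nqo1, at 0.02, was at -0.085 without AA replicate 2, -0.061 without AA replicate 3, -0.024 without DMSO replicate 2 and -0.125 without DMSO replicate 3, and up to 0.21 without the others.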

Other observations

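The genes named in this part were chosen after their values were seen, from lists fixed before. At 72 h transporters and enzymes of the proximal tubule went both ways, 3 up and 3 down of 8 tested. The amino acid transporter gene Slc7a9 rose by 3.11 ± 0.21 from near the floor and Gatm, of creatine synthesis, by 2.05 ± 0.33, while the bicarbonate cotransporter gene Slc4a4 fell to -2.76 ± 0.20 and Aqp1 to -2.33 ± 0.28. Of 11 kidney injury markers 6 rose and 0 fell, with 6 up and 2 down adjusted over the list alone, among them Cd44 (2.30) and Clu (0.67). Of 19 apoptosis regulators 9 rose and 2 fell, among them the p53 target Bbc3 (2.20), Bcl2l1 (1.34) and Bid (1.08), with Mcl1 at -0.42. Of 10 genes of AA activation and organic anion transport 6 rose and 3 fell; the reductase gene Por rose by 1.01 and the efflux transporter gene Abcg2 by 1.89. These lists did not pass camera at 72 h (adjusted p = 0.815, 0.103, 0.0985 and 0.133), and the actin 3' minus 5' measure was 0.65 higher in AA at this time.

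Of 25 interferon response genes 10 rose and 4 fell at 72 h, among them Isg20 (3.14), Isg15 (2.52), Tap1 (2.42) and Irf7 (1.79), without passing camera (adjusted p = 0.214). Of 13 Wnt and Notch targets 9 rose and 3 fell, among them Notch1 (2.23) and Wnt4 (2.03), with Wnt5a at -1.44 (camera adjusted p = 0.103). In the TGF-beta list 9 of 23 genes rose and 6 fell; Ltbp1 was at -1.55 and Smad7 at 0.69 (camera adjusted p = 0.949). In the matrix list 9 of 29 rose and 6 fell (camera adjusted p = 0.870), and 7 of 25 nucleotide excision repair genes rose and 5 fell (camera adjusted p = 0.953), the sign of that median turning with the scaling.

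In lists with too few tested members for a test, values at 72 h did not pass for the AhR targets Tiparp (0.30, adjusted p = 0.197), Cyp1b1 (0.21, adjusted p = 0.445) and Aldh3a1 (-0.04, near the floor). Among marker genes of other cell types, the endothelial Tek fell to -2.02 and Egfl7 did not pass (0.29, adjusted p = 0.219). The macrophage gene Cd68 rose by 1.90 from near the floor. Of loop, distal and collecting duct genes, Gata3 rose by 0.54 and Trpv5, near the floor, by 0.56. Of histone genes, H2az1 fell to -0.20, and Hist2h2be (0.06, adjusted p = 0.852) and H2ac25 (0.07, adjusted p = 0.846) did not pass. The BioB hybridisation control was 0.49 higher in AA at 72 h (exact permutation p = 0.1) and the hexokinase 3' minus 5' difference 0.26 higher (exact permutation p = 0.3).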
